A study of Mus musculus with 4 samples.

How the data were processed

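Olfactory bulb sections of 10 µm from 4 mice of a GFAP reporter strain, aged 4 months, were profiled on spatial arrays of 4992 spots, per the labels. The groups were virgin (n = 2), perinatal care (n = 1) and peri-weaning (n = 1), with 1 library per mouse. UMI counts per gene and spot were deposited by the authors, who, per the submitters' processing notes, made them with Space Ranger 1.2.0 on the mm10 genome and analysed them with Seurat 4.0.0. The matrices held 32285 genes with whole-number counts and only spots over tissue, and a second copy of each matrix was identical. Gene IDs were kept throughout, since 38 symbols belonged to more than 1 ID. Y-linked genes gave 4, 0, 1 and 1 UMIs in virgin 1, virgin 2, perinatal care and peri-weaning, and Xist gave 5850, 1927, 3051 and 2182.

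Sequencing depth ranged from 12655868 UMIs in virgin 2 to 25945629 in virgin 1, so that 3 counts stood for 0.24 and 0.12 counts per 1000000 UMIs (CPM). Counts were summed over all spots of a library, since spots of a section are not replicates. Genes were filtered with filterByExpr (minimum count 10) and tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests on TMM-normalised sums, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each mother was compared with the virgins in a fit with 3 groups, where the spread came from the virgins alone and a lone mother was assumed to vary like them. Mothers were compared with virgins in a fit with 2 groups, where differences between the maternal stages count as spread. The common coefficient of variation was 0.119 and 0.101 in these fits. Peri-weaning and perinatal care were compared as log2 ratios without a test (mean CPM at least 5, pseudocount 0.1 CPM, 1.5-fold), beside the same ratios between the virgins. Both single-mother comparisons share the virgin libraries and are not independent.

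Counts were simulated under 1 common dispersion, with some genes of a mean count of at least 20 raised or lowered. The whole-section fits recovered 17.9% of genes changed 1.5-fold and 80.6% of those changed 2-fold for perinatal care, 16.4% and 65.7% for peri-weaning, and 31.3% and 89.6% for mothers against virgins. Recovery was not simulated for genes of lower count. Unchanged genes called beside these numbered 3 of 15757, 6 of 15756 and 2 of 15407. In region 1 the numbers were 10 of 12737 for perinatal care and 11 of 12420 for mothers, and in region 10 they were 10 of 9058 and 7 of 8545. With no gene changed, 20 simulated data sets per fit gave at most 1 call over the whole section and in region 10 and 0 in region 1, under 1 common dispersion. For lists, camera with its preset correlation found 5 of 5 raised lists and 0 unchanged ones, and with an estimated correlation 0 of 5. Simulated genes varied independently, so this cannot show whether the preset gives false calls for lists of correlated genes.

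Regions came from spots with at least 500 UMIs (9643 of 9680), using scanpy 1.11.5 in Python 3.11.15 with 2000 variable genes scaled within each library, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 0.8, fixed seeds 7 and 11). Regions are named by number and leading genes, and 10 of 15 with at least 30 spots in each library were tested by the same edgeR fits on region sums. Shares are shares of spots, with exact binomial 95% intervals that cover counting error alone. Of 29 gene lists fixed before the data were examined, 28 with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), and the Y-linked list was not tested. List percentiles came from 10000 random lists matched on expression. Some lists share genes, for example Sox10 in the oligodendrocyte, precursor and ensheathing lists. Locations are mm10 coordinates of the GENCODE annotation, matched by gene ID.

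Genes were named by a rule fixed before the data were examined. For each whole-section comparison these were the 12 higher and 12 lower called genes with the largest absolute log2 fold change, a mean CPM of at least 5 and the same sign against each virgin (for mothers against virgins, in all 4 mother to virgin ratios). Places left free went to genes not called, ranked by their smallest ratio over library pairs and given as values. For each region and comparison the top 2 in each direction were taken, from each list the 2 members per direction with the smallest p, and in every comparison Dcx, Sox11, Th, Calb2, Calb1, Gad1, Mki67, Gfap, Cx3cr1, Mbp, Omp, Fos and Prlr. Called genes with a mean CPM under 5 (Camp, Ngp, Trim5, Prl, Fggy, Cyp2a5, Tafa1, Gh, Gm41561, Gm8113, Olfr209, Bglap, Gpat2 and Gm50250), other genes of the stretch of chromosome 17, and genes named within regions for recurring in several were chosen after their values were seen. Folds against virgins with 0 counts were computed on a floor of 3 counts over both virgins, and ratios to 1 to 3 counts carry a 95% counting interval.

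Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and its Wald test, no low-count filter and a mean CPM of at least 10 or 20, libraries thinned to 12655868 UMIs, equal spots per region (1866 per library), removal of mitochondrial, ribosomal and haemoglobin genes, Leiden resolutions of 0.4 and 1.2, scaling over all spots, estimated list correlation, and leaving out libraries. Removal of the spots richest in neutrophil genes, and leaving out libraries for region pairs and lists, were added after the data were seen. Counts of called genes were not set against other splits of the samples, since no group reaches 3 animals, while genes at 2-fold or more between pairs of libraries were counted for all 3 pairings. Images and the staining were not analysed, and 1 gene called lower at peri-weaning is not reported here.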

Results

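Spatial transcriptomes were collected from the olfactory bulbs of 4 mice aged 4 months, with 1 section and 1 library per animal. The olfactory bulb receives the axons of odour-sensing neurons and, in adult mice, neurons born elsewhere in the brain. Both virgin mice form the control group (n = 2), 1 mother was taken during perinatal care (n = 1) and 1 mother at peri-weaning (n = 1). Each library counts unique molecular identifiers (UMIs) per gene at spots spaced 100 µm apart. Virgin 1 gave 25945629 UMIs over 2540 spots under tissue, with a median of 9676 UMIs per spot. Virgin 2 gave 12655868 UMIs over 2369 spots, with a median of 5191. The perinatal care library gave 17697447 UMIs over 2123 spots, with a median of 8046. The peri-weaning library gave 14788316 UMIs over 2648 spots, with a median of 5295. Levels below are counts per 1000000 UMIs (CPM), scaled by trimmed mean of M-values (TMM). Errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of the edgeR F statistic. A count of 0 allowed up to 3 counts, or 0.12 CPM in virgin 1, 0.24 in virgin 2, 0.17 in the perinatal care library and 0.2 in the peri-weaning library, from counting error alone.

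The spots of the 4 sections fell into 15 regions, 10 of which held at least 30 spots in every library and could be compared. Region 1, led by Ly6g6e, Shisa6, Gal and Trh, held 8 of 10 glomerular layer markers at 1.5-fold or more over the other spots. Region 3 was led by the granule cell gene Pcp4 and Stxbp6. Granule cell layer markers at 1.5-fold or more numbered 7 of 10 in region 3, 8 of 10 in region 4 and 4 of 10 in region 9. The name granule region 3 below therefore does not set it apart from region 4. Omp, the olfactory marker protein of sensory axons, and Kctd12 and Clca3a1 led region 5. The mitral cell genes Shisa3, Nefm and Lbhd2 stood out in region 6. Ptgds, Dcn and Igf2, which meningeal fibroblasts express, led region 7, and the migrating neuroblast genes Sox11 and Igfbpl1 led region 10. At 1.5-fold or more, region 7 held 10 of 10 markers of meninges and vessels and 10 of 10 of the olfactory nerve layer. Region 10 held 10 of 10 markers of the rostral migratory stream and 10 of 10 of white matter. The names meningeal and neuroblast region below are therefore short labels for mixed spots. Region 10 took 3.75% of spots in virgin 1 (exact binomial 95% interval 3.04 to 4.57) and 2.54% in virgin 2 (1.94 to 3.26). Its share was 2.99% in the perinatal care library (2.31 to 3.81) and 3.56% in the peri-weaning library (2.89 to 4.34), so both mothers lay between the virgins. Region 7 took 9.08% of spots in virgin 1, 7.49% in virgin 2 and 7.46% in the perinatal care library, against 3.9% in the peri-weaning library (3.19 to 4.71). Region 15, led by Enc1, C1ql3, Bhlhe22 and Mal2, held 142 spots of virgin 1 and 0 spots of the other libraries, which allows up to 0.16% of spots in virgin 2 by the exact binomial interval. Region 12, led by C1ql3, Htr2c and Enc1, held 6 spots of virgin 1, 146 of virgin 2, 1 of the perinatal care library and 38 of the peri-weaning library. The map of regions shows this unequal coverage.

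**Figure D1:**
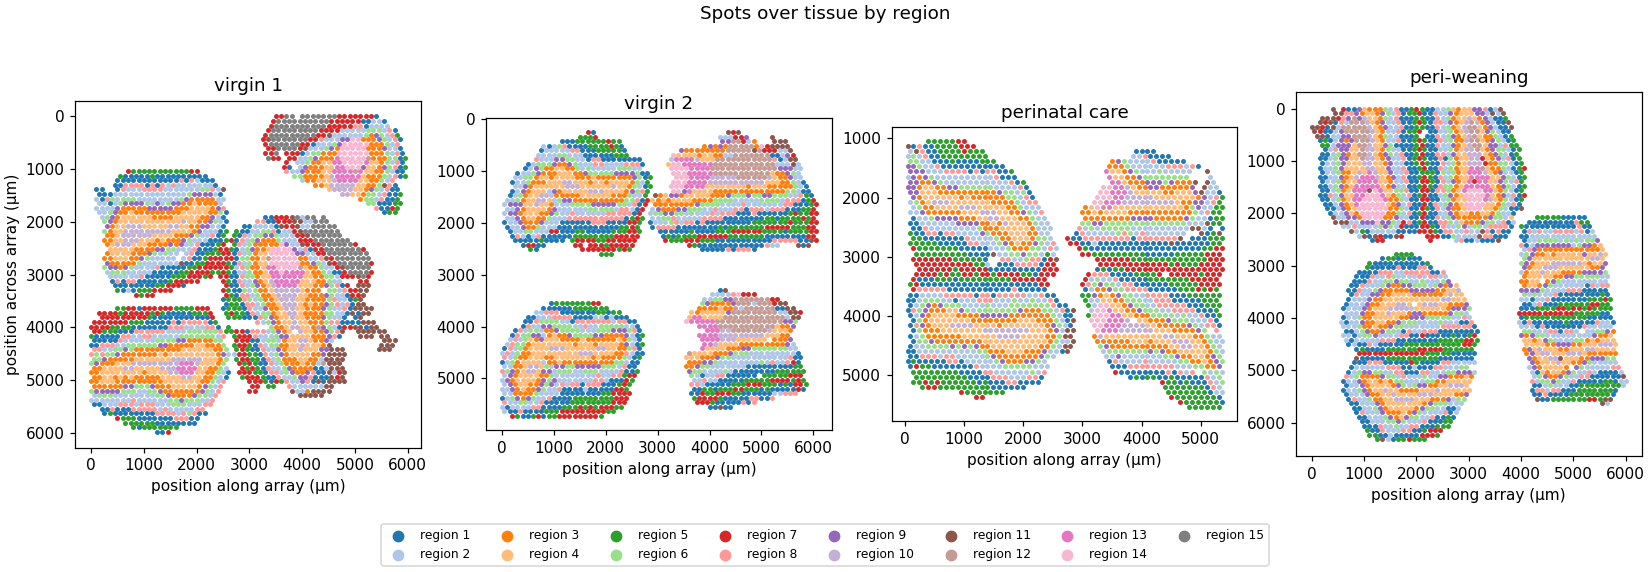
Spots of each library at their positions in the section (both axes in µm), coloured by region. The 4 sections share regions 1 to 10, while region 15 appears in virgin 1 and not in the other libraries.

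The first comparison asks which genes set both mothers apart from both virgins, whatever the stage of motherhood. The neutrophil genes S100a9 and S100a8, which encode the subunits of calprotectin, were higher in both mothers by 4.70 ± 0.30 and 4.11 ± 0.28 on the log2 scale. Nr4a3, a nuclear receptor gene induced by neuronal activity, rose by 2.02 ± 0.17, from 7.99 and 5.67 CPM in the virgins to 30.53 in the perinatal care mother and 26.11 in the peri-weaning mother. These 3 genes were the only ones among 15502 to pass the test (adjusted p = 0.00279, 0.00279 and 0.0115, each higher in 2 of 2 mothers), and edgeR called 0 genes lower, with 619 genes in both directions at an unadjusted p under 0.05 and 26 called by DESeq2. S100a9 (ENSMUSG00000056071) lies on chromosome 3 from 90692632 to 90695721 in mm10, S100a8 (ENSMUSG00000056054) on chromosome 3 from 90668978 to 90670035, and Nr4a3 (ENSMUSG00000028341) on chromosome 4 from 48045153 to 48086447. Both calprotectin calls were lost when the spot richest in neutrophil genes was left out of each library, with log2 fold changes of 4.23 for S100a9 and 3.77 for S100a8, and when equal spots were drawn per region. The Nr4a3 call was lost at a mean CPM of at least 10 (log2 2.00) and after thinning all libraries to the depth of virgin 2 (log2 1.89). Several genes lay on 1 side in both mothers without passing the test. Among those, the AP-1 subunit gene Fosl2 had a log2 fold change of 1.28 ± 0.16 (adjusted p = 0.106), the collagen VI gene Col6a1 0.77 ± 0.11 (adjusted p = 0.226) and the sensory axon gene S100a5 0.67 ± 0.11 (adjusted p = 0.226). Nt5dc3 stood at -0.85 ± 0.10 (adjusted p = 0.0785), the mucin gene Muc3a at -1.77 (adjusted p = 0.226), the transcription factor gene Bhlhe22 at -1.38 (adjusted p = 0.298) and Cd74, the invariant chain of MHC class II, at -0.95 (adjusted p = 0.336). Bhlhe22 is a leading gene of regions 12 and 15. Region 15 held 142 spots of virgin 1 and 0 of each other library. Region 12 held 6 spots of virgin 1, 146 of virgin 2, 1 of perinatal care and 38 of peri-weaning. The difference in Bhlhe22 therefore cannot be told apart from section coverage. Calls rest on a spread with 2 residual degrees of freedom, and they numbered 147 without virgin 1, 52 without virgin 2, 45 without the perinatal care library and 13 without the peri-weaning library, each set including the same 3 genes.

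**Figure D2:**
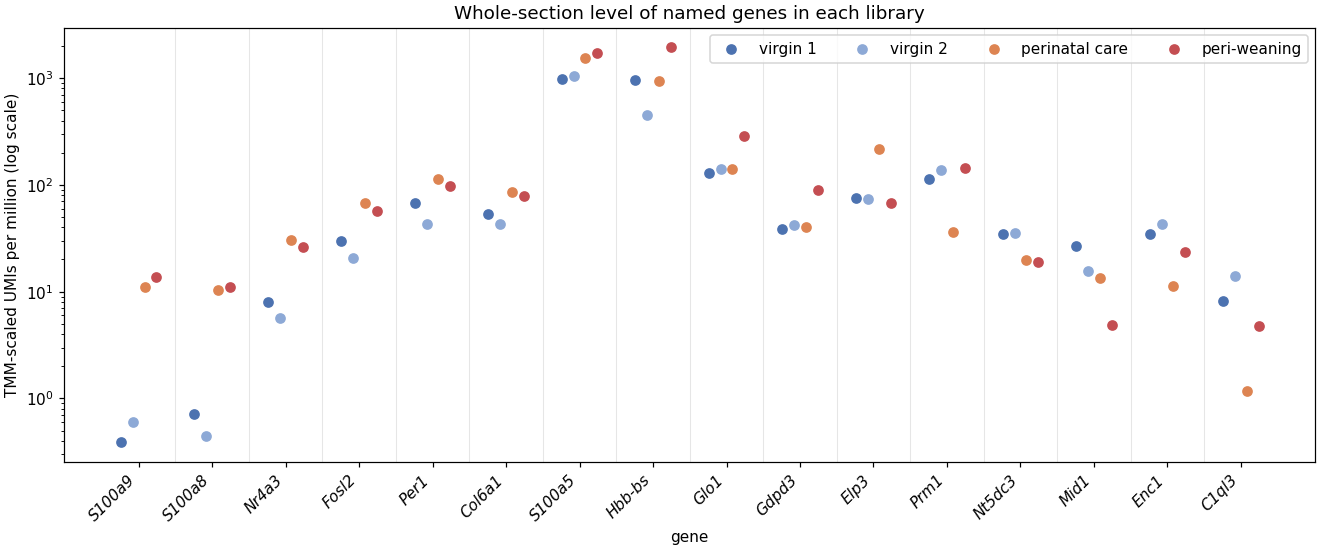
TMM-scaled CPM (log axis) of 16 named genes, with 1 point per library. S100a8, S100a9 and Nr4a3 lie higher in both mothers than in both virgins, while Elp3 and Prm1 stand apart in the perinatal care library and Glo1 and Gdpd3 in the peri-weaning library.

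Among genes tied to the birth and identity of bulb neurons, Dcx, Calb2 and Gad1 were near their virgin levels in both mothers, while Th lay above and Calb1 below both virgins without a call. Dcx, a microtubule protein of migrating neuroblasts, had 181.02 and 161.73 CPM in the virgins, 175.6 in the perinatal care mother and 178.58 in the peri-weaning mother. Its log2 fold changes were 0.03 ± 0.14 at perinatal care and 0.06 ± 0.14 at peri-weaning. The log2 fold changes of Sox11, a neuroblast transcription factor gene, were -0.22 ± 0.17 and -0.15 ± 0.17. Th, the rate-limiting enzyme of dopamine synthesis, had 202.76 and 270.84 CPM in the virgins, 328.51 at perinatal care and 308.01 at peri-weaning. Its fold changes (log2 0.47 ± 0.16, adjusted p = 0.88, and 0.38 ± 0.16, adjusted p = 0.991) were of the size of the difference between the virgins (log2 0.42). Calb2 (0.06 and 0.05), Gad1 (-0.04 and 0.02) and Cx3cr1, a microglial receptor gene (0.04 and 0), were close to 0 on the log2 scale, and Calb1 stood at -0.33 and -0.43. Gfap, the astrocyte filament gene, was at -0.34 ± 0.09 in mothers against virgins (adjusted p = 0.956), Mbp of myelin at -0.26 ± 0.10 and Omp at -0.02 ± 0.26 (both adjusted p = 0.999). The proliferation gene Mki67 averaged 0.75 CPM and stood at -0.37 ± 0.51 in mothers against virgins (adjusted p = 0.999), and the prolactin receptor gene Prlr fell under the count filter. Fos, an early marker of neuronal firing, had 115.17 CPM in virgin 1 and 9 in virgin 2 (log2 ratio -3.66), against 67.15 and 89.33 in the mothers (0.29 ± 0.76, adjusted p = 0.999). None of the tested genes of this set passed edgeR's threshold in any of the 3 comparisons.

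Of the gene lists, 10 were called in mothers against virgins under camera with its preset correlation, most of them with small median shifts, and 0 with an estimated correlation. Ribosomal protein genes had a median log2 fold change of 0.17 (30 of 30 positive, adjusted p = 2e-12), nuclear genes of oxidative phosphorylation 0.13 (30 of 30, adjusted p = 4.73e-08) and blood genes 0.75 (6 of 6, adjusted p = 6.38e-06). Immediate early genes, which neuronal firing induces, had a median of 0.19 (adjusted p = 2.51e-10), with 1 member called over all genes and 2, Nr4a3 and Fosl2, when adjusted over the list alone. Periglomerular dopaminergic interneuron genes had 0.07 (adjusted p = 0.00449), with 0 members called over all genes and 2 adjusted over the list alone, Nr4a2 at 0.68 and Trh at 0.59. Mitral and tufted cell genes had 0.12 (adjusted p = 0.00563), with 0 members over all genes and 1, Shisa3 at 0.52, adjusted over the list alone. Heat shock genes had 0.13 (adjusted p = 0.0194). Lower lists were oligodendrocytes at -0.18 (18 of 20 negative, adjusted p = 1.65e-05, Mog at -0.30), anterior olfactory nucleus and cortical neurons at -0.12 (adjusted p = 0.0319) and mitochondrially encoded oxidative phosphorylation at -0.11 (adjusted p = 0.0498). Adjusted over the list alone, the anterior olfactory nucleus list had 0 members called lower and 1 called higher, against its direction. Markers of the anterior olfactory nucleus or cortex at 1.5-fold or more numbered 6 of 10 in region 12 and 8 of 10 in region 15, which the sections covered unequally. All 10 calls were lost when the correlation was estimated from the residuals (adjusted p = 0.899 with an estimated correlation for the mitochondrially encoded list and 0.752 for the other 9). Immediate early and blood genes also set the virgins apart, with medians of -1.58 and -1.25 in virgin 2 against virgin 1. The virgins also lay at least as far apart as mothers from virgins in the mitochondrially encoded (-0.37), mitral and tufted (0.20), ribosomal (-0.17), heat shock (-0.17) and anterior olfactory nucleus (-0.15) lists, and less far in the oligodendrocyte (0.12), periglomerular (0.01) and nuclear oxidative phosphorylation (-0.06) lists. Without virgin 2 the immediate early list turned to lower (adjusted p = 0.000366), the blood (adjusted p = 0.114), oligodendrocyte (adjusted p = 0.157) and heat shock (adjusted p = 0.612) calls ended. Without virgin 1 the periglomerular (adjusted p = 0.0563), mitral and tufted (adjusted p = 0.774, direction turned) and mitochondrially encoded (adjusted p = 0.214, direction turned) calls ended. Leaving out the perinatal care library ended the anterior olfactory nucleus call (adjusted p = 0.281) and the mitochondrially encoded call (adjusted p = 0.15), and leaving out the peri-weaning library ended those of mitral and tufted cells (adjusted p = 0.416) and heat shock (adjusted p = 0.198). Ribosomal proteins and nuclear oxidative phosphorylation kept their direction and call without any 1 of the 4 libraries. With equal spots per region the periglomerular (adjusted p = 0.0575), mitral and tufted (adjusted p = 0.11) and anterior olfactory nucleus (adjusted p = 0.095) calls ended and the other 7 held.

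The other 18 lists did not pass the test between mothers and virgins. Median log2 fold changes were 0.04 for immature neurons (adjusted p = 0.182), -0.18 for cell cycle genes (adjusted p = 0.0822), -0.07 for neural stem cells and progenitors (adjusted p = 0.298), 0.04 for granule cell layer interneurons (adjusted p = 0.0521) and -0.08 for oligodendrocyte precursors (adjusted p = 0.236). Homeostatic microglia stood at -0.04, phagocytic and activated microglia at 0.06, endothelial and mural cells at -0.02, meningeal fibroblasts at -0.11, choroid plexus at -0.25, interferon response at 0.03, apoptosis at 0.05, cholesterol synthesis at -0.05 and synaptic genes at 0.00, with adjusted p from 0.168 to 0.97. Median and test differed in sign for astrocytes (0.02, test lower), olfactory ensheathing cells (0.02, test lower), olfactory sensory neuron axons (-0.01, test higher) and prolactin, oestrogen and oxytocin signalling (-0.08, test higher), with adjusted p from 0.611 to 0.98. With equal spots per region the meningeal list became higher in mothers (adjusted p = 1.56e-06).

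**Figure D3:**
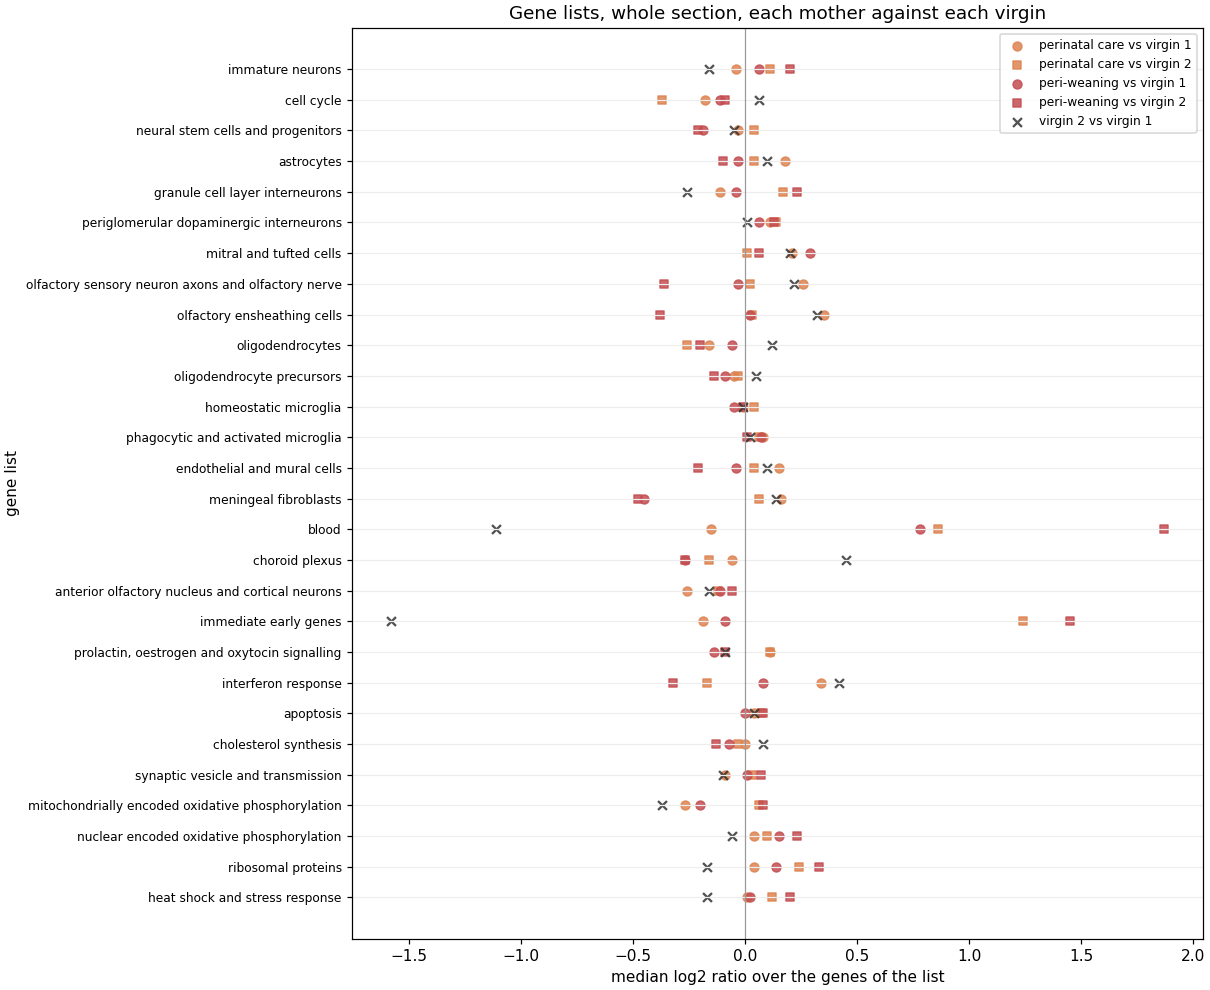
Median log2 ratio of each of 28 gene lists for each mother against each virgin (points), with virgin 2 against virgin 1 as crosses. Immediate early and blood genes differ between the virgins by more than most lists differ between mothers and virgins.

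The mother in perinatal care was compared with the virgins to ask what the bulb expresses while pups need full care. Besides S100a9 (log2 4.55 ± 0.36), S100a8 (4.07 ± 0.36) and Nr4a3 (2.13 ± 0.19), this animal had more Elp3, the catalytic subunit of Elongator, at 215.83 CPM against 75.88 and 73.27 in the virgins (log2 1.53 ± 0.14). The activity-induced gene Fosl2 rose by 1.40 ± 0.16 and the circadian clock gene Per1 by 1.02 ± 0.18. Prm1, a protamine gene best known from sperm chromatin, fell by 1.80 on the log2 scale, to 36.23 CPM from 113.49 and 138.82. C1ql3, a synaptic organiser gene, fell by 3.20, Mal2 by 2.15 and Enc1 by 1.76, and these lead regions 12 and 15, which the perinatal care section covered with 1 and 0 spots. In all, 15 genes were higher and 7 lower among 16042 tested (436 at an unadjusted p under 0.05). Adjusted p was 2.85e-07 for S100a9, 8.59e-07 for S100a8, Nr4a3 and Elp3, 1.71e-06 for Prm1, 5.33e-05 for Fosl2, 0.0148 for Per1 and 0.000193 for C1ql3. Elp3 (ENSMUSG00000022031) lies on chromosome 14 from 65530449 to 65593075, Prm1 (ENSMUSG00000022501) on chromosome 16 from 10796326 to 10805839, and Fosl2 (ENSMUSG00000029135) on chromosome 5 from 32135801 to 32157842. Smaller rises were those of Col6a1 (0.82 ± 0.15, adjusted p = 0.0214), Midn (0.74 ± 0.14, adjusted p = 0.0316) and Slc2a1, the glucose transporter of the blood-brain barrier (0.71 ± 0.14, adjusted p = 0.0418). Nt5dc3 fell by 0.82 and Acaa1a by 0.74. Among genes of low count, the neutrophil granule genes Camp (37 UMIs against 0 in both virgins together) and Ngp (25 against 0) were at least 26.9-fold and at least 18.2-fold higher on a floor of 3 counts over both virgins, and Trim5 (33 against 0) at least 24-fold. With the counting error of the mother's own UMIs the lower 95% limits were 20.8 for Camp, 13.7 for Ngp and 18.4 for Trim5. In this library 1 spot held 61.2% of the UMIs of S100a8, S100a9, Camp and Ngp together, which counting error does not cover. Prl, the prolactin gene, had 22 UMIs against 2, a ratio of 24 (counting interval 5.9 to 210). Fggy, Cyp2a5 and Tafa1 were called as well, the last being lower and a leading gene of region 12. For each of the 22 genes the gap between the mother and the nearer virgin exceeded the gap between the virgins. The test assumes that a lone mother varies as the virgins do, and 0 genes passed it when all libraries were thinned to the depth of virgin 2, where edgeR had 339 genes at an unadjusted p under 0.05 and DESeq2 at full depth called 8.

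With the preset correlation, and not with an estimated one, lists called higher in the perinatal care mother included vessels, meninges and ribosomal proteins. As long as regions were not balanced, they also included sensory axons and glia. Median log2 fold changes were 0.17 for olfactory ensheathing cells (13 of 16 positive, adjusted p = 2.89e-05), 0.14 for ribosomal proteins (28 of 30, adjusted p = 0.000111), 0.08 for periglomerular dopaminergic interneurons (adjusted p = 0.0035), 0.13 for olfactory sensory neuron axons (adjusted p = 0.0138) and 0.11 for astrocytes (adjusted p = 0.0239). Endothelial and mural cells had 0.08 (adjusted p = 0.00664), meningeal fibroblasts 0.08 (adjusted p = 0.00834), blood 0.25 (adjusted p = 0.0138), interferon response 0.08 (adjusted p = 0.0221), nuclear oxidative phosphorylation 0.06 (adjusted p = 0.0411) and immediate early genes 0.06 (adjusted p = 1.97e-10). For 3 of these lists the mother lay on opposite sides of the virgins, with medians against virgin 1 and virgin 2 of -0.19 and 1.24 for immediate early genes, -0.15 and 0.86 for blood, and 0.34 and -0.17 for interferon response. Medians were also uneven for ribosomal proteins (0.04 and 0.24), sensory axons (0.26 and 0.02), ensheathing cells (0.35 and 0.03) and astrocytes (0.18 and 0.04). The same held for endothelial and mural cells (0.15 and 0.04), meningeal fibroblasts (0.16 and 0.06) and nuclear oxidative phosphorylation (0.04 and 0.1). Periglomerular interneurons (0.11 and 0.14) were more even. Over all genes, 1 endothelial member (Slc2a1), 1 meningeal member (Col6a1) and 2 immediate early members (Nr4a3 and Fosl2) were called. Adjusted over the list alone, each of these lists had 2 called members. Trh at 0.62 and Nr4a2 at 0.66 of the periglomerular list, Cdh19 at 0.65 and Apod at 0.52 of the ensheathing list, Ifi27l2a at 0.94 and H2-D1 at 0.53 of the interferon list, S100a5 at 0.59 of the axon list and Agt at 0.59 of the astrocyte list were called over the list alone and not over all genes. Oligodendrocyte genes were lower with a median of -0.22 (16 of 20 negative, adjusted p = 0.000111), with Mag at -0.37 and Mog at -0.40. Anterior olfactory nucleus and cortical neurons (-0.16, adjusted p = 0.000185), cell cycle genes (-0.28, adjusted p = 0.0341) and mitochondrially encoded oxidative phosphorylation (-0.11, adjusted p = 0.0411) were lower too, the last with -0.27 against virgin 1 and 0.06 against virgin 2. In the cortical list, Tbr1 at -0.81, Neurod2 at -1.62 and, against the list's direction, Cux2 at 0.72 were called over the list alone. These 15 calls were lost with a correlation estimated from the residuals (adjusted p = 0.871 with an estimated correlation for the mitochondrially encoded list and 0.84 for the other 14). With equal spots per region 7 remained. Lost were the oligodendrocyte and cortical lists (both adjusted p = 0.133), ensheathing cells and nuclear oxidative phosphorylation (both adjusted p = 0.126), sensory axons (adjusted p = 0.595), astrocytes (adjusted p = 0.272), interferon response (adjusted p = 0.431) and periglomerular interneurons (adjusted p = 0.056). Immature neurons (0.02, adjusted p = 0.91), neural stem cells and progenitors (0.01, adjusted p = 0.417) and granule cell layer interneurons (0.01, adjusted p = 0.686) did not pass. The medians of choroid plexus (-0.06, test higher) and phagocytic microglia (0.10, mean -0.02) differed in sign from the test or the mean, and neither passed.

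The mother at peri-weaning was set against the virgins to ask what the bulb expresses once pups leave the nest. Besides S100a9 (log2 4.83 ± 0.36), S100a8 (4.17 ± 0.36), Nr4a3 (1.90 ± 0.19) and Fosl2 (1.15 ± 0.17), this animal had 284.69 CPM of Glo1, the glyoxalase that detoxifies methylglyoxal, against 128.57 and 140.03 in the virgins (log2 1.08 ± 0.14). Gdpd3, a lipid phosphodiesterase gene, had 88.63 against 38.39 and 41.96 (1.14 ± 0.14). Gm10503, a transcript antisense to Glp1r and Umodl1, had 384 UMIs against 0 in both virgins together, at least 334-fold higher on a floor of 3 counts over both virgins. The X-linked ubiquitin ligase gene Mid1 fell by 2.15 on the log2 scale, Muc3a by 2.25, and the olfactory nerve gene Clca3a1 by 0.89. In all, 22 genes were higher and 9 lower of 16042 tested (704 at an unadjusted p under 0.05). Adjusted p was 1.42e-10 for Gm10503, 4.17e-08 for S100a9, 5.71e-07 for S100a8, 6.38e-06 for Nr4a3, 0.000103 for Gdpd3, 0.000206 for Glo1, 0.000242 for Mid1, 0.000994 for Fosl2 and 0.00575 for Muc3a. Glo1 lies on chromosome 17 from 30584936 to 30626871, Gm50250 from 30450398 to 30457877, Gm41561 from 30848436 to 30857436 and Gm10503 from 30920338 to 30963220, so 4 called genes shared a stretch of 513 kb. Gm50250 (117 UMIs against 0) was at least 102-fold higher and Gm41561 (32 against 1) had a ratio of 83.5 (counting interval 14 to 3400), and the strand of antisense reads makes their assignment uncertain. Mid1 (ENSMUSG00000035299) lies on chromosome X from 169685199 to 170005736 and Gdpd3 (ENSMUSG00000030703) on chromosome 7 from 126766334 to 126775649. The haemoglobin genes Hbb-bs (1.45 ± 0.24, adjusted p = 0.00575) and Hba-a1 (1.28 ± 0.23, adjusted p = 0.0108) and the odorant receptor gene Olfr3 (4.90 ± 0.59, adjusted p = 8.75e-05) were higher as well, with gaps no larger than the difference between the virgins. S100a5 rose by 0.75 ± 0.15 (adjusted p = 0.0294) and Dusp6, a phosphatase of activated ERK, by 0.73 (adjusted p = 0.0481). Prl had 116 UMIs against 2, a ratio of 151 (counting interval 41 to 1260). Gh, the growth hormone gene, had 30 against 0 and Camp 34 against 0, at least 26.1-fold and at least 29.6-fold higher on the same floor. With the counting error of the mother's own UMIs the lower 95% limits were 270 for Gm10503, 81.5 for Gm50250, 19.9 for Gh and 22.8 for Camp. The remaining higher genes were Olfr209, Bglap, Gpat2 and the paralogs Gm7324 (1.08 ± 0.19) and Gm8113 (47 UMIs against 3, ratio 40.9, counting interval 13.2 to 205), whose reads cannot be separated with certainty. Apoc1 fell by 1.33, Egfl8 by 1.27, Slc22a6 by 0.98, Commd7 by 0.87 and Nt5dc3 by 0.87. With equal spots per region Slc22a6 stood at -0.21 and Egfl8 at -0.77. This comparison too treats 1 mother as varying like the virgins, and 3 of the 31 genes were called after thinning to the depth of virgin 2.

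The neutrophil genes and Prl were sparse, and most spots held none of their UMIs. S100a8, S100a9, Camp and Ngp together had 28 UMIs in virgin 1, 14 in virgin 2, 443 in the perinatal care library and 402 in the peri-weaning library, on 20, 10, 80 and 116 spots. In region 1 of the perinatal care section 1 spot held 271 of the 443, and in region 7 of the peri-weaning section 1 spot held 105 of the 402. Prl had 1 UMI in each virgin, 22 on 19 spots at perinatal care and 116 on 66 spots at peri-weaning, with at most 13 in a spot. Meningeal region 7 held 89.3% of the neutrophil gene UMIs of virgin 1 and 35.7% of those of virgin 2, against 11.3% at perinatal care and 41.5% at peri-weaning. It held 54.5% of the Prl UMIs at perinatal care, with 7.46% of the spots, and 10.3% of those at peri-weaning, with 3.9% of the spots.

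**Figure D4:**
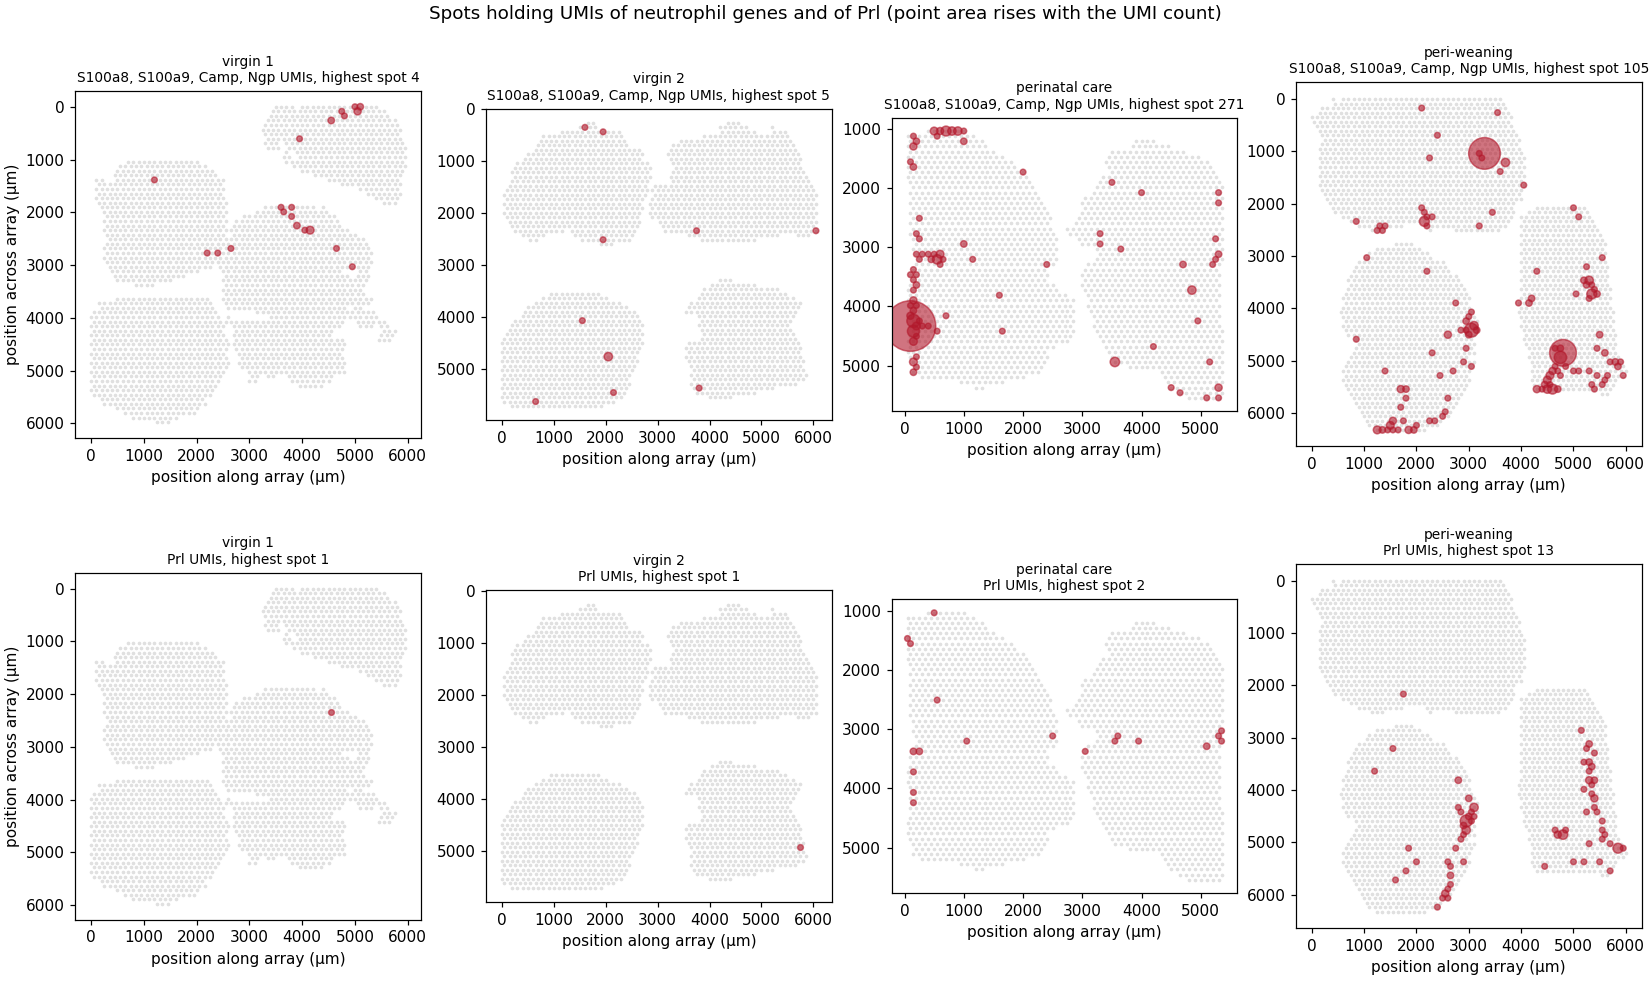
Positions of spots with UMIs of the neutrophil genes S100a8, S100a9, Camp and Ngp, and of Prl, in each library, with point area rising with the UMI count. The perinatal care section has 1 spot that outweighs all others for the neutrophil genes.

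At peri-weaning, under camera with its preset correlation, lists were called higher for blood, translation and respiration, and lower for meninges and glia of the olfactory nerve. No call was kept with an estimated correlation. With equal spots per region the meningeal list turned to higher and the ensheathing call ended. Blood genes had a median log2 fold change of 1.28 (7 of 7 positive, adjusted p = 7.36e-22), with 2 members called over all genes and 5 adjusted over the list alone. Immediate early genes had a median of 0.24 (adjusted p = 1.45e-14), which rests on virgin 2, with -0.09 against virgin 1 and 1.45 against virgin 2. Medians were 0.23 for ribosomal proteins (30 of 30, adjusted p = 3.1e-11), 0.20 for nuclear oxidative phosphorylation (30 of 30, adjusted p = 9.97e-09), 0.17 for mitral and tufted cells (adjusted p = 0.00276), 0.08 for granule cell layer interneurons (adjusted p = 0.0107), 0.10 for heat shock (adjusted p = 0.0107), 0.05 for periglomerular dopaminergic interneurons (adjusted p = 0.0371) and 0.08 for immature neurons (adjusted p = 0.0414). The immature neuron list had 14 of 20 members positive, 0 called over all genes and 0 adjusted over the list alone. Meningeal fibroblasts were lower with a median of -0.47 (adjusted p = 4.22e-10), with 0 members called over all genes and 11 lower and 2 higher adjusted over the list alone, among them Igf2 at -0.67 and Ptgds at -0.71 against Col6a1 at 0.71 and Col1a1 at 0.59. Olfactory ensheathing cells (-0.24, adjusted p = 3.69e-05), endothelial and mural cells (-0.17, adjusted p = 0.00276), oligodendrocytes (-0.12, 18 of 20 negative, adjusted p = 0.0107), neural stem cells and progenitors (-0.21, adjusted p = 0.016), oligodendrocyte precursors (-0.10, adjusted p = 0.0414) and choroid plexus (-0.49, adjusted p = 0.0424) were lower. The granule cell layer call (-0.04 against virgin 1 and 0.23 against virgin 2), the ensheathing call (0.02 and -0.38) and the heat shock call (0.02 and 0.2) rest on virgin 2. In larger part so do the immature neuron (0.06 and 0.2), endothelial and mural (-0.04 and -0.21) and oligodendrocyte (-0.06 and -0.2) calls. The mitral and tufted call (0.29 and 0.06) rests in larger part on virgin 1. Within the stem cell list Fabp7 stood at -0.45 and Id1, called over the list alone, at 0.56. Within the precursor list Matn4 at -0.84, and within the choroid plexus list the transthyretin gene Ttr at -2.05, were called over the list alone. These 16 calls were lost with a correlation estimated from the residuals (adjusted p from 0.766 to 0.784 with an estimated correlation). Meningeal spots were scarcer in this section (3.9% in region 7), and with equal spots per region the meningeal list turned to higher (adjusted p = 3.66e-07). The ensheathing, stem cell, precursor and mitral and tufted lists (each adjusted p = 0.0939), oligodendrocytes (adjusted p = 0.0921), immature neurons (adjusted p = 0.358), granule cell layer interneurons (adjusted p = 0.232), periglomerular interneurons (adjusted p = 0.185), endothelial and mural cells (adjusted p = 0.326) and choroid plexus (adjusted p = 0.921) no longer passed with equal spots, while blood, immediate early, ribosomal, nuclear oxidative phosphorylation and heat shock genes did. Median and test differed in sign for homeostatic microglia (-0.02, test higher, adjusted p = 0.983), and median and mean for synaptic genes (0.04 and -0.01, adjusted p = 0.941).

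Between the mothers, peri-weaning was set against perinatal care with 1 animal on each side, so that the ratios compare animals, and no test was run. The peri-weaning mother had more Prm1 (log2 ratio 2.00) and less Elp3 (-1.68), Mid1 (-1.44), the lipoprotein gene Apoc1 (-1.37) and the neural crest transcription factor gene Foxd3 (-1.24). Of 11788 genes with a mean of at least 5 CPM, 282 differed by 1.5-fold or more, 61 higher at peri-weaning and 221 higher at perinatal care. The same count between the virgins was 351, so the mothers differed from each other in fewer genes than the virgins did. The largest ratios were those of Gm10503 (7.42), Gm10320 (5.96, against 6.31 between the virgins) and Olfr3 (3.19, against 3.99). Htr2c, a serotonin receptor gene and leader of region 12, had 1.89 against 2.97 between the virgins. Scgb1c1 (-2.21 against 2.10) and Lyrm7 (-1.37 against 1.82) likewise differed between the virgins by as much or nearly so. Genes lying outside the range of the other 3 libraries by 1.5-fold numbered 21 for perinatal care and 54 for peri-weaning, against 56 for virgin 1 and 67 for virgin 2. With equal spots per region the count between the mothers was 151, with 52 higher at peri-weaning and 99 at perinatal care, against 284 between the virgins.

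Within regions, the comparison of mothers with virgins asks where in the bulb the difference lies. Nr4a3 was higher in 6 of 10 regions, among them region 9 (led by Tpbg and Sema3c, log2 2.84 ± 0.47, adjusted p = 0.00573), region 4 (Adamts5 and Nrgn, 2.65 ± 0.28, adjusted p = 8.22e-05) and granule region 3 (2.52 ± 0.31, adjusted p = 0.00187). The errors of these 3 overlap, so they are not ranked. In region 9 the virgins had 4.8 and 1.4 CPM and the mothers 25.8 and 28, against 50.4 and 33.4 for the mothers in region 4. Virgin 2 had 113 spots in region 9 at a median of 5912 UMIs. The 1.4 CPM there thus stand for very few UMIs, and the size of that fold is uncertain. Gng4, a G protein gamma subunit gene, was also higher in 6 regions, by 0.96 ± 0.14 in olfactory nerve region 5 (adjusted p = 0.00238), 0.79 ± 0.14 in neuroblast region 10 (adjusted p = 0.00165) and 0.64 ± 0.10 in region 3 (adjusted p = 0.00927). Sst, the somatostatin gene, rose in region 10 from 43.1 and 32.1 CPM in the virgins to 118.4 and 156.9 in the mothers (1.78 ± 0.25, adjusted p = 1.03e-05) and in region 5 from 14.7 and 15.8 to 35.7 and 45.4 (1.36 ± 0.28, adjusted p = 0.0436). The other 8 regions did not pass for Sst, with values from -0.89 ± 0.26 in region 4 (adjusted p = 0.397) to 0.84 ± 0.19 in region 1 (adjusted p = 0.14). S100a5 rose in 5 regions outside the olfactory nerve, by 1.18 ± 0.13 in region 8 (Cbln4 and Cck, adjusted p = 1.37e-05), 1.24 ± 0.12 in region 2 (Vip and Pvalb, adjusted p = 1.91e-05) and 1.62 ± 0.22 in region 4 (adjusted p = 0.00112). Its levels there were far below those of olfactory nerve region 5. Region 4 had 24.6 and 23.1 CPM in the virgins, 54.3 at perinatal care and 93.2 at peri-weaning. Region 5 had 6127.2 and 4560.4 in the virgins, 6920.7 at perinatal care and 9886.9 at peri-weaning. Which cells these low levels come from was not tested. Fosl2 and Per1 were each higher in 5 regions, with 1.54 ± 0.20 for Fosl2 in region 2 (adjusted p = 0.000613) and 1.41 ± 0.27 for Per1 in region 10 (adjusted p = 0.00403). Col6a1 was higher in regions 3, 4 (0.89 ± 0.13, adjusted p = 0.00387) and 5. Aqp1, a water channel gene, and Spp1, the osteopontin gene, were higher in meningeal region 7 (1.31 ± 0.22 and 1.16 ± 0.20, both adjusted p = 0.0435), as was S100a9 (3.99 ± 0.72, adjusted p = 0.0435). In region 10, Nr4a1 (1.54 ± 0.24, adjusted p = 0.000129) and Egr1 (1.04 ± 0.21, adjusted p = 0.0113) were called, but virgin 2 had 12.8 CPM of Nr4a1 against 95.2 in virgin 1. Lower calls with a gap beyond the virgin difference were Bri3bp in region 4 (-0.68 ± 0.13, adjusted p = 0.0246) and Nt5dc3 in region 9 (-1.61 ± 0.33, adjusted p = 0.036). Across the 10 regions 60 gene and region pairs were higher and 7 lower, covering 29 genes, and 43 of the 67 had a gap beyond the difference between the virgins. In simulated data 11 unchanged genes were called in region 1 and 7 in region 10 beside the changed ones, and 0 in both with no gene changed. Those data gave every gene the same dispersion. They therefore cannot show how many of the 67 pairs are false calls where genes differ in their spread between animals. Called pairs numbered 451 without virgin 1, 471 without virgin 2, 242 without the perinatal care library and 115 without the peri-weaning library. Of the 67 pairs, 57 were also called with DESeq2 size factors, 48 without virgin 1, 54 without virgin 2, 55 without the perinatal care library and 39 without the peri-weaning library. In region 5 Gng4 was the 1 call of 11 left with DESeq2 size factors, where Sst and Col6a1 each had adjusted p = 0.0794, and Gng4 there was not called without the peri-weaning library (adjusted p = 0.398). Nr4a3 in region 4, Sst in region 10, S100a5 in regions 2 and 4, Fosl2 in region 2, Col6a1 in region 4 and Nr4a1 in region 10 were called under all of these settings, and each other pair named here was lost under at least 1.

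**Figure D5:**
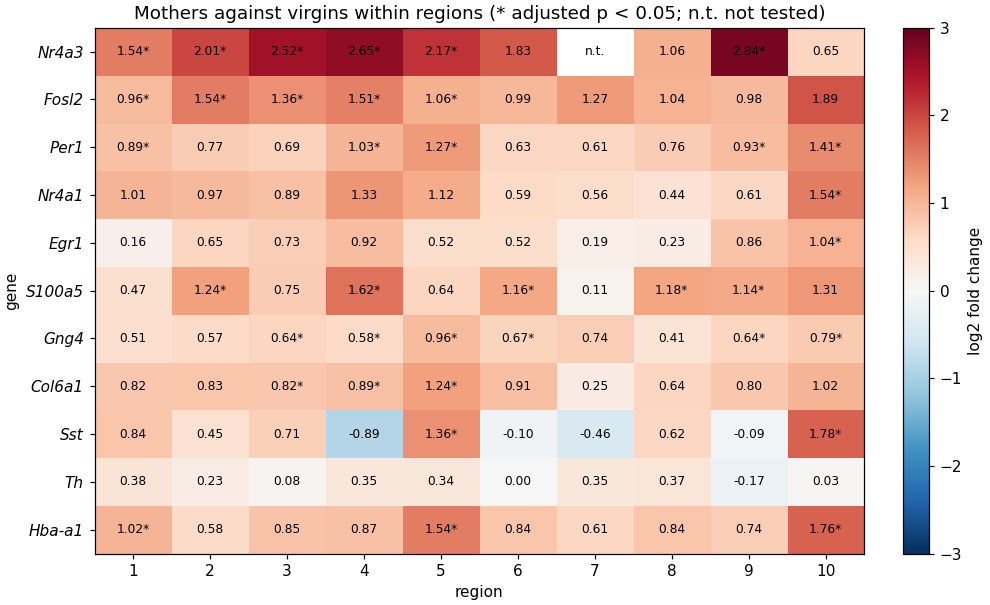
Log2 fold change of mothers against virgins for 11 genes (rows) in regions 1 to 10 (columns), with a star where adjusted p was under 0.05 and n.t. where a gene was not tested. Nr4a3 and Gng4 carry a star in 6 regions each, and Sst in regions 5 and 10, while in region 5 only Gng4 keeps its star with DESeq2 size factors.

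Each mother was also compared with the virgins region by region. These fits borrow the spread across genes and hold 1 mother, so a small p does not measure how far animals vary in that gene. Genes far apart in the virgins were called too, such as Gm34121 in region 3, with 0.7 and 27.2 CPM in the virgins and 0 at perinatal care. In the perinatal care mother Prm1 was lower in 10 of 10 regions, by -2.52 ± 0.27 in region 4, and Elp3 was higher in 8, by 2.16 ± 0.16 in granule region 3. Nr4a1 and S100a5 in 5 regions each and Egr1 in 4 were called higher without a call over the whole section. For Nr4a1 in region 10 this mother had 231 CPM, against 95.2 in virgin 1 and 12.8 in virgin 2. Immediate early genes differed widely between the virgins over the whole section (median log2 ratio -1.58 in virgin 2 against virgin 1). Aqp1 in region 7 stood at 1.46 ± 0.24 (adjusted p = 0.00831). S100a9 reached 48.9 CPM in glomerular region 1 against 0 in both virgins, where 1 spot held 61.2% of the library's UMIs of S100a8, S100a9, Camp and Ngp. In the peri-weaning mother Hba-a1 was higher in 10 regions, Hbb-bs in 9, Glo1 and Gm10503 in 8 and Gdpd3 in 7, and Mid1 was lower in 4, by -3.48 ± 0.50 in region 3 (adjusted p = 6.67e-09). Cwc22, lower in 7 regions, and Nr4a1, higher in 5, had no call over the whole section, where Cwc22 had 18.17 CPM in this mother against 64.48 in virgin 1 and 19.51 in virgin 2. Olfr3 reached 111 CPM in region 1, against 0 in both virgins and 0.3 in the perinatal care library. The perinatal care comparison gave 93 higher and 35 lower pairs over 55 genes, of which 76 exceeded the virgin difference, and the peri-weaning comparison 156 higher and 49 lower over 90 genes, of which 124 did. AA465934, a processed transcript called lower in 8 regions in each mother and in 5 in mothers against virgins, had 100.9 CPM in region 3 of virgin 1 and 14.7 in virgin 2, against 7.5 and 9.2 in the mothers, so its gap did not exceed the difference between the virgins.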

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

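Gene lists that moved in opposite directions in the mothers against the same virgins were noted by rule, and the tests on blood, on pituitary hormones and all 3 tests on genes apart in 1 mother were chosen only after the result was seen. Endothelial and mural cell genes had a median log2 fold change of 0.08 at perinatal care and -0.17 at peri-weaning, meningeal fibroblast genes 0.08 and -0.47, and olfactory ensheathing cell genes 0.17 and -0.24. The difference between the mothers was not tested, and each stage has 1 animal. The virgins lay 0.32 apart for the ensheathing list, where perinatal care was at 0.03 against virgin 2 and peri-weaning at 0.02 against virgin 1. With equal spots per region the meningeal list was higher at peri-weaning too (adjusted p = 3.66e-07, with a range over this list's alternatives from 5.83e-11 to 0.766).

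The neutrophil genes S100a8, S100a9, Camp and Ngp were higher in both mothers. The tables argue against more blood of the virgins' make-up left in the mothers' sections, since the lowest mother's UMIs of these genes per haemoglobin UMI were 6.54 times the highest virgin's. The ratio cannot exclude blood or a clot richer in neutrophils. The spot with most UMIs of these genes held 370 haemoglobin UMIs at peri-weaning, above 99.5% of spots, and 72 at perinatal care, above 94.1%. In virgin 1 and virgin 2 that spot held 6 and 0. Their UMIs were concentrated, with 74.9% at peri-weaning and 85.3% at perinatal care in the top 1% of spots, as a fragment or clot over a few spots would give, although sparse genes concentrate by counting alone and all virgin UMIs of these genes lay in the top 1% of spots as well. Bone marrow carried onto the section stays open: precursor genes had an upper limit of 112% of granule genes, but Prtn3 had like levels in the virgins, which voids the criterion set beforehand, so the reading was changed from met to undecided after the value was seen, and the other precursors were near absent at perinatal care and peri-weaning (Mpo 1 and 0 UMIs, Elane 1 and 3, Ctsg 0 and 1, beside Camp at 37 and 34), which speaks against marrow from few counts. Neutrophils in or on the tissue of mothers are another open explanation, untested here.

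Prl UMIs were found in both mothers, with 22 and 116 against 1 in each virgin. Of the pituitary hormone genes Gh, Pomc and Cga, 1 (Gh, 30 UMIs) lay above both virgins at peri-weaning, between the bounds set for pituitary RNA carried onto the section, so this cannot be told apart from other sources. Pomc could not inform this test, since before TMM scaling it had 7.32 and 8.06 CPM in the virgins and 7.78 at peri-weaning. A trace of pituitary RNA would be hidden in that background. Cga had 1 UMI at peri-weaning. Within 500 µm of the spot with most Prl lay 31.0% of its UMIs and 2.45% of the spots, which falls between the bounds set for a fragment on the section. Prl was detected on 36.4% of the 22 spots with Gh and on 2.21% of the other spots, a comparison also made after the result was seen. Transcription of Prl in the bulb of a mother stays open and was not tested.

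Genes called in 1 mother, at a mean CPM of at least 5 and with the other mother within 0.5 of the virgins on the log2 scale, numbered 15, among them Elp3, Prm1, Acaa1a and Slc2a1 at perinatal care and Glo1, Gdpd3, Clca3a1, Gm7324, Hba-a1 and Hbb-bs at peri-weaning. The part of the bulb that the section covers is argued against as their common cause, since with equal spots per region the median size of their log2 fold changes was 1.03 against 1.14, or 90.4%, although Slc22a6 kept 21.4% of its size, Egfl8 60.6% and Clca3a1 67.4%. Whether inherited variants underlie some stays open. Splits of 2-fold or more followed the groups 2.0 times as often as the more frequent other pairing (6 genes against 3 and 2). Bhlhe22 among the 6, and Htr2c among the other pairings, lead regions that the sections covered unequally. None of the 15 genes is among those split 2 libraries against 2, so this count cannot decide their cause. The sign of the 15 held in a median of 100% of regions, but haemoglobin genes met that part too, so it is not specific. Calls made on sums over these regions also favour such agreement. At peri-weaning an inherited copy number difference of a stretch of chromosome 17 stays open, as 4 of 16 genes (of any level) called higher in that mother and not called in the other lay within 1 Mb against at most 3 in 10000 random draws, and Glo1 at 1.08 ± 0.14 was within 2 standard errors of a doubling. Of these 4 only Glo1 was near a doubling. Gm10503 was at least 334-fold and Gm50250 at least 102-fold higher, and Gm41561 had a ratio of 83.5. Against a doubling of the whole stretch, Dnah8 inside it (0.02 ± 0.46) and Btbd9 (0.21 ± 0.14), Glp1r (-0.31 ± 0.55) and Umodl1 (-3.52 ± 1.38), which lie in or across it, were near or below the virgin level, while Gm50240 inside it (0.85 ± 0.27, not called, adjusted p = 0.474) was within 1 standard error of a doubling, and the reading was changed from met to undecided after these values, most from low counts, were seen; maternal stage stays open for all of these genes, untested.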

How the results depend on the processing

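Removal of the spots richest in neutrophil genes, and leaving out libraries for region pairs and lists, were settings chosen only after the results were seen. Of 642 values of named genes under alternatives, 412 kept direction and side of the threshold, 193 fell short of it and 37 without a test moved by more than the replicate spread. For lists, 344 of 448 values were kept, 78 fell short and 22 newly passed. The 22 genes called at perinatal care became 8 with the DESeq2 Wald test, 80 with no low-count filter, 5 at a mean CPM of at least 10, 0 after thinning (edgeR, with 339 genes at an unadjusted p under 0.05), 14 with equal spots per region, 11 without mitochondrial, ribosomal and haemoglobin genes, 9 without the spot with most neutrophil-gene UMIs, 12 without the top 1 percent of such spots and 13 without the peri-weaning library. The 31 genes at peri-weaning became 14, 113, 3 and 3 under the Wald test, no filter, the CPM minimum and thinning, 17 without the top spot, and between 23 and 45 under the others. The 3 genes that set mothers apart became 26 with the Wald test, 175 with no filter and 0 at a mean CPM of at least 10 (edgeR, with 408 genes at an unadjusted p under 0.05), where S100a8 and S100a9 fall under the minimum and Nr4a3 (log2 2.00) is tested but not called. Nr4a3 was the 1 gene left with equal spots, without the top spot and without the top 1 percent, and thinning left S100a8 and S100a9 and ended the Nr4a3 call (log2 1.89). Removing the top 1 percent took away every virgin UMI of the neutrophil genes, so their folds there cannot be read. Leaving out each library in turn gave 13 to 147 genes, including the same 3 each time. No paired analysis was possible because each mouse gave 1 section. Genes at 1.5-fold between the mothers fell from 282 to 151 with equal spots and 82 at a mean CPM of at least 20. Genes with 1 library apart numbered 10 for perinatal care and 31 for peri-weaning with equal spots, and 15, 31, 8 and 12 for virgin 1, virgin 2, perinatal care and peri-weaning at a mean CPM of at least 20. Gene and region pairs in mothers against virgins went from 67 to 106 with genes scaled over all spots and 351 with no filter, and spanned 115 to 471 with a library left out. With DESeq2 size factors 59 pairs were called, 57 of them shared with the 67, and region 5 went from 11 calls to 1. With an estimated correlation 0 lists were called by camera (limma) in perinatal care, 0 in peri-weaning and 0 in mothers, a setting that found 0 of 5 raised lists in simulated data. Genes varied independently in those data, while the estimated correlation in mothers against virgins reached 0.957 for blood genes. The simulation therefore cannot back the calls made with the preset. Equal spots per region left 7 of 15 lists at perinatal care, gave 6 at peri-weaning, of which 5 were among the 16 and the meningeal list had turned, and gave 8 for mothers, of which 7 were among the 10, and leaving out libraries gave 10 to 16 for mothers, against 10 with all of them. Direction turned for meningeal fibroblasts at peri-weaning with equal spots (adjusted p = 3.66e-07), which evens out the scarce meningeal spots. In mothers it turned for mitral and tufted cells without virgin 1 (adjusted p = 0.774, range without each library 6.51e-08 to 0.774), immediate early genes without virgin 2 (adjusted p = 0.000366, range 4.43e-152 to 0.000366) and mitochondrially encoded oxidative phosphorylation without virgin 1 (adjusted p = 0.214, range 4.96e-08 to 0.214). The meningeal list, lower but not called in mothers, also turned to higher there with equal spots. Filters and thinning change the genes and counts tested by construction, and for the other changes the cause was not tested. Whether depth itself ends the single-mother calls on thinning was not tested, and settings that hardly change depth, such as leaving out 1 spot per library, ended many too. The single-mother fits over the whole section recovered under 20% of simulated 1.5-fold changes, where depth was not set apart from the lone animal and the few degrees of freedom.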
